A study of Mus musculus with 2 samples.

How the data were processed

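ATAC-seq was performed on mouse (C57BL/6) prostate tumor cells after 2 weeks (W2) or 6 months (M6) of tamoxifen, with 1 library per time point. Per the labels' protocols, nuclei were released with a detergent buffer containing digitonin to lower mitochondrial DNA, and libraries were made with a commercial transposase kit. Per the submitters' processing notes, Trim Galore 0.5.0, Bowtie2, SAMtools 1.4 and deepTools were used and the genome build was mm10. The notes give no order or role of these tools as used here. The peak caller, its version, its threshold, the handling of duplicate reads and any shift of read ends for the transposase are not given in the sources used here. Peaks were deposited per library, so nothing was pooled.

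Each deposited list gave, per peak, the interval, a score, a fold, a −log10 p, a −log10 q and the summit. The fold that the authors deposited is a linear ratio of the summit over the local background of the same library. The −log10 p and −log10 q values deposited for each peak come from the caller of the authors, and the lowest −log10 q was 1.47 in W2 and 1.38 in M6. The score deposited with each peak differed from 10 times the −log10 q by at most 1 and was not used further. These values served to describe, rank and filter peaks within a list. Neither list held duplicate intervals. Peaks on chromosomes 1 to 19, X and Y were analysed (5735 and 22570), and 30 W2 and 24 M6 peaks on other sequences were left out.

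No read depth was given. The pileup at the summit and the local background were recovered for every peak from the fold and the −log10 p, taking the fold as (pileup + 1)/(background + 1) and the p as the upper tail of a Poisson distribution. A whole-number pileup was found for 100% of the peaks of both libraries within 0.001 of the deposited −log10 p, which also shows that the pileups were not scaled. On simulated data the step recovered 100% of 2000 peaks, and real W2 peaks paired with a shifted p gave a whole pileup in 0.2%. Pileups started at 12 tags in W2 and 10 in M6, so regions with fewer tags are outside both lists. The lowest background, a genome-wide floor reached by 19.2% of W2 and 16.1% of M6 peaks, was 2.96 and 2.65 tags and was read as relative depth. A background of at least 3 times the library median was called raised, which applied to 11 W2 and 219 M6 peaks, and runs of at least 10 raised peaks with gaps under 500 kb were called segments. Both rules were set after the data were seen. Backgrounds moved in steps of 0.02 tags, as tags of 200 bp counted over 10 kb would give. To find the background left outside called peaks, the summit pileup of each called peak within 10 kb around a summit, spread over its width and 200 bp on either side, was subtracted.

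Peaks overlapping by at least 1 bp were called shared. Because the libraries differed in peak number, the main comparisons used an equal number of peaks, the 5735 with the highest −log10 q in each list, and the comparison of all peaks is given beside it. For M6 this kept peaks with a −log10 q of at least 10.8. Genes came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes on these chromosomes. The table gives gene starts and ends without strand, exons or sequence. The planned promoter window was therefore replaced by 1 kb on either side of both annotated gene ends, random lists were matched on gene length in 5 classes without CpG content, and motifs, exons and introns were not analysed here. A locus is a gene body with 10 kb on either side.

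The 13 gene lists (neuroendocrine, neuronal transcription factor, luminal, basal, epithelial-mesenchymal transition, fibroblast, smooth muscle, leukocyte, endothelial, cell cycle, housekeeping, immediate early and stress, and hepatocyte genes) were fixed before the data were examined, as were the designs and most of the other settings tried. For each list, the number of genes with a gene-end peak in M6 minus W2, and the mean difference in peaks per locus, were placed among 10000 random lists of the same size as a percentile. In 100 simulated lists of 38 genes with a known gain (18% with a W2 peak, 45% with an M6 peak), 90% lay above the middle 95% of random lists, and 4% of unchanged lists lay outside it. These rates do not carry over to lists with fewer peaks or a smaller gain. With equal numbers of peaks, the neuroendocrine list had 2 of 38 genes in W2 and 5 in M6. Where peaks of random genes fall in number, this percentile runs high for genes that have none in either library, and where they rise it runs low. A comparison added after the data were seen took the genes of a list with an M6 gene-end peak, counted those that also had one in W2, and placed the share among random sets with M6 peaks in the same of 10 classes of −log10 q.

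Since each time point had 1 library, no test of the time points was made and no p-value across genes is given. Shares carry exact (Clopper-Pearson) binomial 95% intervals, which cover counting error only. The genes named in the text are a set chosen before the data were examined (Foxa2, Kit, Chga, Syp, Insm1, Krt8, Krt5, Trp63, Trp53, Rb1 and Myc), up to 4 per list with the highest −log10 q among gene-end peaks of 1 library and none in the full list of the other, and the genes nearest to the 10 strongest peaks of each library without a counterpart; other genes are marked as chosen afterwards, and genes of the chromosome 4 segments were also chosen afterwards. Some genes that this rule names are not reported here. Alternatives covered the overlap rule, a −log10 q of at least 5 or 10, windows of 500 bp, 2.5 kb and 50 kb, the ranking value, the equal number, all peaks, and leaving out peaks with raised background. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.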

Results

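Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in prostate tumor cells of C57BL/6 mice. The series follows progression toward neuroendocrine prostate cancer (NEPC), a prostate cancer that carries markers of nerve and hormone-secreting cells. It holds 2 libraries. W2 came from cells of the early stage, treated with tamoxifen for 2 weeks, and M6 from cells of the late stage, treated for 6 months. Whether the cells of either library were taken directly from tumors or were cultured is not given in the sources used here. Each time point had 1 library, so no difference below has a replicate check, and intervals cover counting error only. The deposited lists held 5765 peaks for W2 and 22594 for M6, of which 5735 and 22570 lay on chromosomes 1 to 19, X and Y of mm10. The number of sequenced reads is not given in the sources used here. The genome-wide background that the peak statistics imply was 2.96 tags in W2 and 2.65 tags in M6, a ratio of 0.895, so M6 was not the deeper library by this measure.

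The opening question was how the accessible regions of the late-stage cells compared with those of the early stage. M6 had 3.94 times as many peaks as W2, and they covered 8733 kb against 1834 kb. Most W2 regions were still among the M6 peaks: 4618 of 5735 W2 peaks (80.5%, exact binomial 95% interval 79.5 to 81.5%) overlapped an M6 peak by at least 1 bp. Conversely, 4552 of the 22570 M6 peaks (20.2%, 19.6 to 20.7%) overlapped a W2 peak, which left 18018 M6 peaks without a W2 counterpart and 1117 W2 peaks without an M6 counterpart. The shared regions were mostly at genes. Of the shared W2 peaks 71.0% lay within 1 kb of an end of a protein-coding gene, against 16.0% of the W2 peaks without an M6 counterpart. In M6 these shares were 71.3% and 28.1%. The strongest peaks were shared most often: 97.6% of the strongest 10% of W2 peaks and 70.6% of the strongest 10% of M6 peaks had a counterpart, against 65.0% and 3.32% of the weakest 10%. With the 5735 strongest peaks of each library by the authors' −log10 q, the shares were 51.8% of W2 and 50.5% of M6 peaks. At the 4618 shared W2 sites the summit pileup, the number of tags over the summit, had a median of 21 in W2 and 32 in M6.

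Regions away from genes made up more of the M6 list. Gene ends held 3460 of the 5735 W2 peaks (60.3%, 59.1 to 61.6%) and 8305 of the 22570 M6 peaks (36.8%, 36.2 to 37.4%). With equal numbers of peaks the M6 share was 53.3% (52.0 to 54.6%), a difference from W2 of −7.03 percentage points. Peaks inside genes but away from their ends made up 22.4% of the W2 list and 25.8% of the equal M6 list, and peaks outside genes 17.2% and 20.9%. Peak positions moved by 1 Mb fell on a gene end in 5.48% (W2) and 4.64% (M6) of cases. In all, 4033 of 21887 protein-coding genes had a gene-end peak in W2 and 8688 in M6.

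Neuroendocrine genes had gene-end peaks mostly in M6. Of 38 genes of this class, 2 had a gene-end peak in W2 and 19 in M6, and every list gene with a W2 gene-end peak also had an M6 one. The 4 strongest M6 gene-end peaks without a W2 counterpart were at Syt1, the calcium sensor of vesicle release, Onecut2, a transcription factor linked to NEPC, Uchl1, a neuronal deubiquitinase, and Sox11, a neural transcription factor. Syt1 had an M6 peak at chromosome 10, 109010356 to 109011740 (fold 6.87 over local background, −log10 q 21.0), and 10 M6 peaks within its body and 10 kb on either side, against 0 in W2. Syt1 is a long gene (108497650 to 109010980), and that count was not adjusted for gene length. The Onecut2 peak (chromosome 18, 64339823 to 64340107) had a −log10 q of 14.1, the Uchl1 peak (chromosome 5, 66676025 to 66676910) one of 11.6 and the Sox11 peak (chromosome 12, 27342658 to 27342924) one of 9.75. Named here after their values were seen, Celsr3, an adhesion receptor of neural cells, and Hes6, a transcription factor of neural differentiation, were the 2 genes with a gene-end peak in both libraries. Other genes of the list with M6 gene-end peaks only, also chosen after their values were seen, were Chgb, Scg2 and Scg5 (secretory granule proteins), Pcsk1 and Pcsk2 (prohormone convertases), Ncam1, Eno2, Srrm4 (a neural splicing factor), Mycn, Ret, Myt1 and Calca. With Kit, described below, these are all the list genes with an M6 gene-end peak. The rest of the 38 had none in either library. Among them were Foxa2, Insm1, Chga and Syp. Neurod1, Sox2, Pou3f2, Nkx2-1, Prox1, Dll3 and Snap25, named after their values were seen, also had none.

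With equal numbers of peaks, 2 neuroendocrine genes had a gene-end peak in W2 and 5 in M6, the additional ones being Syt1, Onecut2 and Uchl1. That difference of 3 lay at percentile 97.0 of 10000 random gene lists of the same size matched on gene length. Ranking peaks by fold in place of −log10 q gave 2 genes in each library. Within gene bodies and 10 kb on either side, 6 list genes had more peaks in M6 and 2 had fewer, from 10 M6 and 6 W2 peaks (percentile 92.0). With all peaks, 72 M6 and 6 W2 peaks lay at these loci. That rise of 66 stood against a median rise of 31 in length-matched random lists (percentile 99.96). Since M6 pileups were higher at shared sites in general, the list was also compared at matched strength, a comparison added after the data were seen. Of the 19 neuroendocrine genes with an M6 gene-end peak, the 2 with one in W2 made 10.5% (exact interval 1.30 to 33.1%). Random sets of genes with M6 gene-end peaks of the same −log10 q had a median of 36.8%, with the middle 95% from 15.8 to 52.6%, and the list lay at percentile 0.275.

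**Figure D1:**
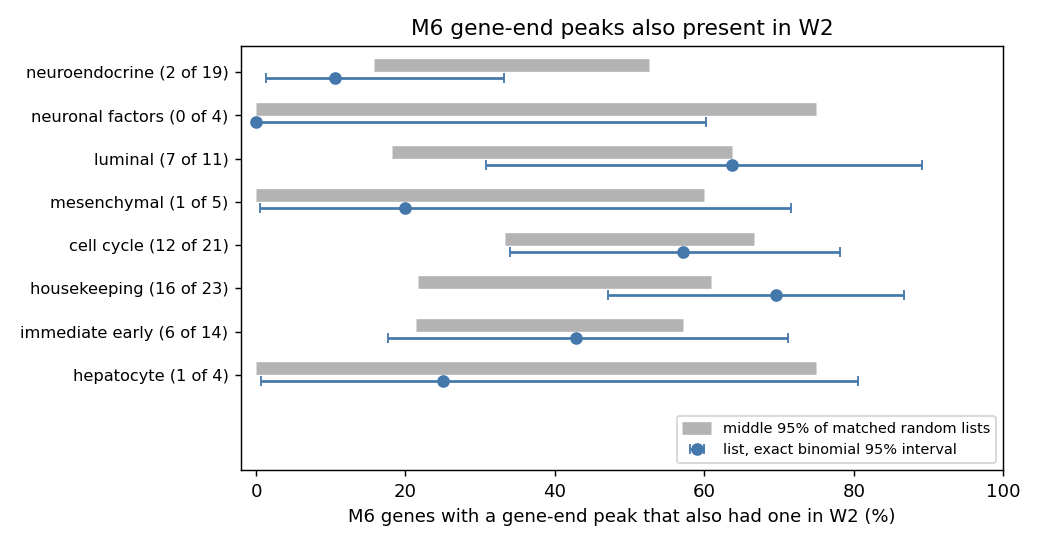
For each gene list, the percentage of genes with an M6 gene-end peak that also had a W2 gene-end peak (points, exact binomial 95% intervals) and the middle 95% of random gene sets matched on the M6 −log10 q (grey bars). The neuroendocrine list, at 2 of 19 genes, sits below its grey bar, and the housekeeping list, at 16 of 23, above it.

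Kit, a receptor tyrosine kinase, had no W2 peak within 50 kb and 5 M6 peaks within its locus. A peak at its annotated start coordinate (chromosome 5, 75574565 to 75575319) had a fold of 4.29, a −log10 q of 8.28 and a pileup of 29 tags over a local background of 6.00. It was the stronger of 2 gene-end peaks and fell below the −log10 q of 10.8 needed for the equal number of M6 peaks. The strongest of the 5, inside the gene (75640334 to 75640827), had a −log10 q of 16.1 and a fold of 7.17. Gene-end peaks were found at 18.4% of all protein-coding genes in W2 and 39.7% in M6. Foxa2, a forkhead factor, had no peak within 50 kb in either library. Chga, the chromogranin A gene, had no gene-end peak in either library, and 2 M6 peaks within 50 kb. Syp, the synaptophysin gene, had 1 peak within its locus in each library, with a −log10 q of 8.56 in W2 and 15.3 in M6. Insm1, a zinc finger factor of neuroendocrine differentiation, had 2 M6 peaks within 10 kb and none in W2.

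**Figure D2:**
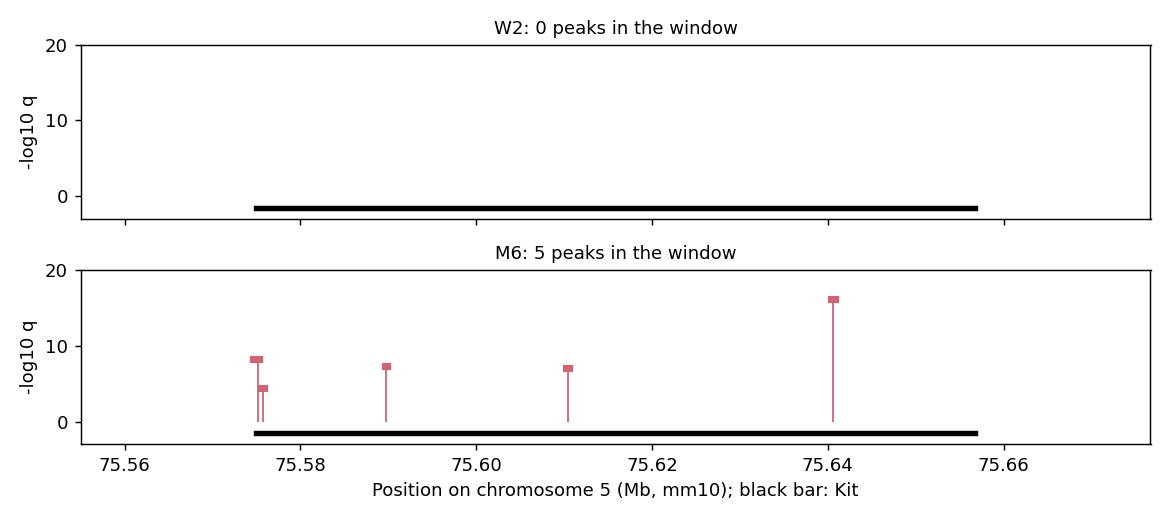
Peaks at the Kit locus on chromosome 5 (mm10) in W2 (top) and M6 (bottom): each bar spans a peak at the height of its −log10 q, the vertical line marks its summit, and the black bar is the annotated gene. W2 has 0 peaks in the window and M6 has 5, the highest at a −log10 q of 16.1.

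Transcription factors of nerve cells, a list of 32 genes, had gene-end peaks at 0 genes in W2 and 4 in M6. These were Neurod4 (−log10 q 11.2), Sox21 (10.0), Sox1 (8.69) and Phox2a (3.85), the last of which shares its peak with the neighbouring Inppl1. Neurod4 alone remained with equal numbers of peaks, which put the list at percentile 82.5. With all peaks, the list's difference of 4 genes lay at percentile 16.7 of length-matched random lists.

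Luminal epithelial genes, the markers of secretory prostate cells, mostly had no gene-end peak in either library. Of 34 genes, 8 had a gene-end peak in W2 and 11 in M6, and 7 of those 11 were present in both (63.6%, 30.8 to 89.1%), at percentile 93.3 of strength-matched sets. With all peaks, the list's difference of 3 genes lay at percentile 5.13 of length-matched lists, and of all protein-coding genes 18.4% had a gene-end peak in W2 and 39.7% in M6. Those 7, chosen after their values were seen, were Cdh1 and Epcam (cell adhesion), Cldn3 (a tight junction claudin), Elf3 and Klf5 (epithelial transcription factors), Fkbp5 and Ndrg1. Gene-end peaks in M6 only were at Cldn7 (−log10 q 17.8), Krt8 (6.05), Grhl2 (5.10) and Cldn4 (3.53). With equal numbers of peaks the list had 8 genes in W2 and 6 in M6 (percentile 22.9), and 21 W2 against 13 M6 peaks at its loci (percentile 1.61). With all peaks the direction turned, to 21 W2 and 43 M6 peaks at the loci.

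Basal epithelial genes had few peaks. Of 20 genes, 1 had a gene-end peak in W2, Krt6a (−log10 q 3.06), and 2 had one in M6, among them the laminin-binding integrin Itga6 (4.68). Krt5, a basal keratin, had no peak within its locus in either library, and Trp63, the basal master regulator, had 2 M6 peaks inside its locus (the stronger with a −log10 q of 13.3) and 0 in W2. Of 16 genes of epithelial-mesenchymal transition, 1 had a gene-end peak in W2 and 5 in M6. M6 alone had peaks at Snai2, a repressor of epithelial genes (−log10 q 11.5), the N-cadherin gene Cdh2 (5.56), Spock1 (4.75) and the fibronectin gene Fn1 (3.97), while Snai1, named after its values were seen, had one in both. With all peaks, the difference of 4 genes in the mesenchymal list equalled the median of length-matched random lists (percentile 59.65). This list had 1 gene in each library with equal numbers of peaks.

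Markers of other cell types that tumor tissue can hold had few gene-end peaks in either library. Leukocyte genes had gene-end peaks at 0 of 22 genes in W2 and 1 in M6, Coro1a (−log10 q 4.27). Endothelial genes had 0 of 15 in both libraries. Fibroblast genes had 0 of 16 in W2 and 1 in M6, Gsn (7.72), an actin regulator also made by epithelia, and smooth muscle genes had 1 of 10 in W2, Smtn (5.83), and 0 in M6. Counted over whole loci with all peaks, endothelial genes had 2 W2 and 12 M6 peaks, with more in M6 at 7 genes and fewer at 0, leukocyte genes 5 and 9, fibroblast genes 1 and 6, and smooth muscle genes 3 and 6. These rises were smaller than the median rise of length-matched random lists. They were 10 against 14 for endothelial, 4 against 14 for leukocyte, 5 against 12 for fibroblast and 3 against 8 for smooth muscle genes. Hepatocyte genes, a control outside the prostate, had 1 of 15 in W2 and 4 in M6, among them Ahsg (9.11) and F2 (7.48).

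Housekeeping and cell cycle genes, used by every dividing cell, and immediate early and stress genes were counted for comparison. Housekeeping genes had gene-end peaks at 16 of 30 genes in W2 and 23 in M6, and all 16 of the W2 genes were among the 23. Gene-end peaks in M6 only included those of Polr2a, the large subunit of RNA polymerase II (−log10 q 12.8), Sdha (8.81), Rps18 (8.31) and Rab7 (7.57). These genes are in use in all cells. The peaks of Polr2a, Sdha and Rps18 are shared with an end of the neighbouring Slc35g3, Ccdc127 and Vps52, respectively. Cell cycle genes had 12 of 26 in W2 and 21 in M6. Peaks in M6 only were strongest at E2f1 (13.3), Mcm6 (12.5), Cdc20 (10.9) and Ccnb2 (9.77). Immediate early and stress genes had 7 of 20 in W2 and 14 in M6, with M6-only peaks at Dusp1 (10.9), Fos (10.8), Jund (8.67) and Junb (7.41) and a W2-only peak at Zfp36 (8.40). With all peaks, their difference of 7 genes lay at percentile 98.95 of length-matched random lists (random median 3). The percentile was 99.905 for neuroendocrine, 92.4 for cell cycle and 70.455 for housekeeping genes. At shared gene-end sites without raised M6 background, the M6 pileup was above that of W2 by a median log2 of 0.58 (n = 3272 sites) and higher at 90.2% of them. With equal numbers of peaks the housekeeping list fell from 16 genes in W2 to 8 in M6, below all 10000 length-matched random lists (percentile 0), the cell cycle list had 12 in both, and the immediate early list had 7 in W2 and 6 in M6.

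**Figure D3:**
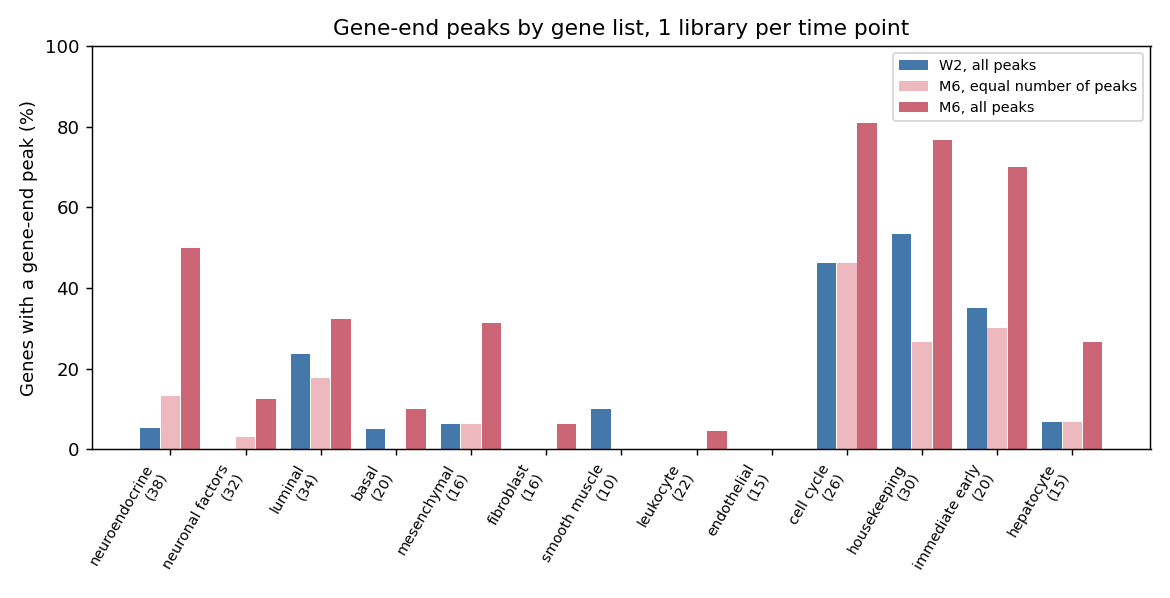
Percentage of genes in each list (number of genes in parentheses) with a gene-end peak in W2, in the equal number of M6 peaks and in all M6 peaks; bars are single libraries, without error bars. Neuroendocrine genes go from 2 of 38 in W2 to 19 of 38 among all M6 peaks, and housekeeping genes from 16 of 30 to 23 of 30.

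Tumor suppressor genes often lost in NEPC had peaks in M6. Trp53 had a gene-end peak in both libraries, shared with the divergent gene Wrap53 (−log10 q 5.90 in W2 and 9.93 in M6). Rb1 had 0 W2 peaks and 3 M6 peaks within its locus, including a weak one at its end (2.08) and one inside the gene (15.3). The proto-oncogene Myc had no peak within 10 kb in either library.

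Among the 10 strongest M6 peaks that overlapped no W2 peak, 5 lay in a pair of stretches of chromosome 4. Those were 3 peaks with Nfib, which encodes a nuclear factor I transcription factor, as the nearest gene, 1 inside Frem1, and 1 at the end of Ppie (chromosome 4, 123139503 to 123140476, −log10 q 38.2). Of the 3, 1 lay outside genes, 224 kb from the end of Nfib, and the others inside it. The folds of these 5 peaks ran from 3.11 to 3.64, against 10.0 to 11.2 for the rest of the 10. The other 5 lay 57.5 kb from Tbc1d30 (chromosome 10, 121205947 to 121206663, −log10 q 40.3), inside Wdr17 (38.3), 165 kb from Diras2 (37.3), 214 kb from Zfp703 (36.6) and at the end of Khdrbs2 (36.1). The corresponding W2 peaks were weaker. The strongest lay 0.756 kb from Spag9 (chromosome 11, 93995149 to 93995457, −log10 q 23.2). The next ones were 109 kb from Rasa1 (15.1), inside Rgs7 (14.8), 41.6 kb from Pfkfb3 (14.6), inside Atxn1 (14.5) and 10.3 kb from Gm39469 (14.5). Others were inside Celf4 (14.4) and Dagla (14.3), at Isg20 (14.0) and 116 kb from Parp11 (13.9). Of the 10 strongest peaks of each whole list, 7 were the same sites.

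The chromosome 4 stretches stood apart in their local background, the tag density around each peak. From 81815783 to 83165450, a segment of 1350 kb with the genes Nfib, Zdhhc21, Cer1 and Frem1, M6 had 121 peaks with a median background of 37.9 tags, 10.8 times the library median of 3.52, and W2 had 0 peaks. From 122699690 to 123637714, a stretch of 938 kb that includes Mycl, a MYC family transcription factor, Cap1 and Trit1, M6 had 65 peaks with a median background of 51.1 tags, 14.5 times the library median. W2 had 10 peaks there, with a median background of 3.87 tags, 1.13 times its library median. Neither segment was raised throughout. Around Mycl the unbroken run of raised peaks ended at 123343533, after 644 kb with 15 genes, and 2 peaks at ordinary background (4.32 and 2.76 tags) in the region of Macf1 separated it from 4 raised peaks from 123633329 to 123637714. Around Nfib, 2 ordinary peaks (median 4.75 tags) from 82011032 to 82013419 parted a run of 188 kb without protein-coding genes from one of 1145 kb with all 4 genes. The 5 nearest M6 peaks on either side of the segments had median backgrounds of 3.72 and 4.26 tags around Nfib and 3.56 and 3.64 around Mycl. The peak at the annotated start of Mycl had a pileup of 20 tags in W2 and 224 in M6, and that at Cap1 36 and 281. Relative to local background both were lower in M6, with folds of 3.87 in W2 and 2.44 in M6 at Mycl and 6.45 and 3.52 at Cap1. No other stretch of M6 peaks above 3 times the library median was longer than 15.5 kb.

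**Figure D4:**
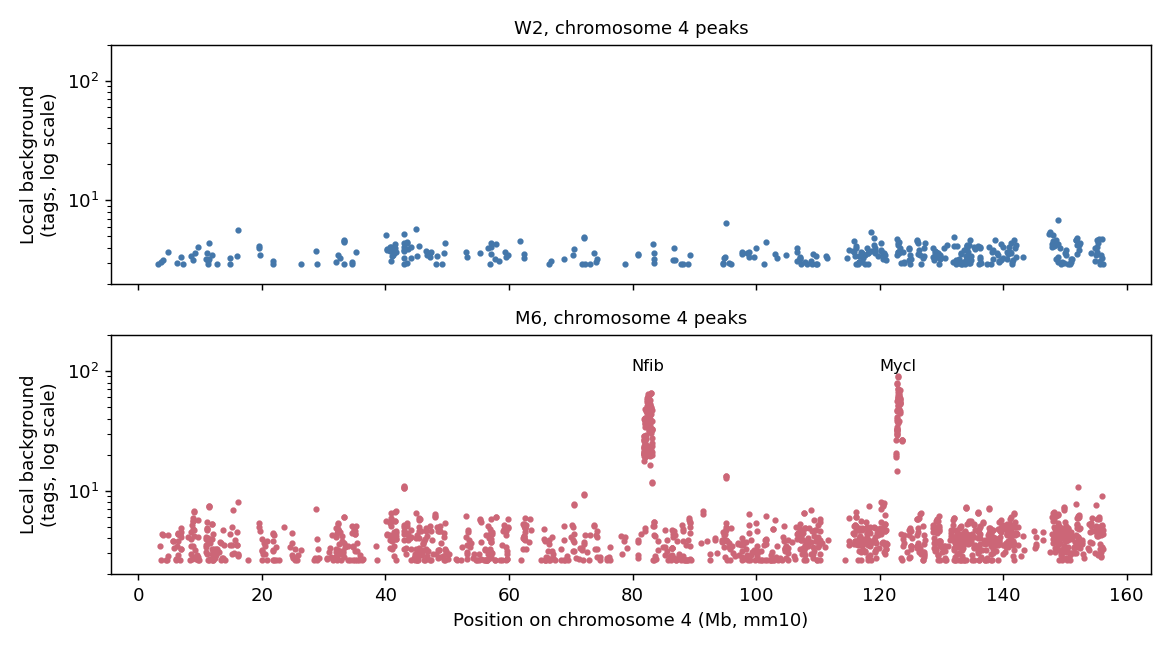
Local background of each chromosome 4 peak (tags, log scale) against its position (Mb, mm10) in W2 (top) and M6 (bottom). M6 peaks reach medians of 37.9 and 51.1 tags in the Nfib and Mycl segments, and the 10 W2 peaks in the Mycl segment have a median of 3.87 tags.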

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

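The tests on the chromosome 4 segments, on the number of peaks and on nerve tissue were chosen after the results were seen. The strength-matched share of neuroendocrine genes was added after the data were seen. The gene counts behind it were known by then, and only the range of the matched sets was new.

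A signal outside the main measurement, the local background, stood out in M6 on chromosome 4. Its median was 10.8 times the library median over the 121 M6 peaks of the Nfib segment and 14.5 times over the 65 of the Mycl segment. On sequences outside chromosomes 1 to 19, X and Y, which no comparison used, W2 had 30 peaks and M6 had 24.

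The raised background of the chromosome 4 segments was weighed against called open elements alone, repeats or mis-mapped reads, and a gain in DNA copies. Called elements alone are argued against: with the tags of called peaks within 10 kb subtracted, assuming a background window of that size, the median background inside was still 7.26 times the library median, while at the 37 other raised M6 peaks it was 0.504 times. Repeats or mis-mapping are argued against for the Mycl segment, where the W2 background was 1.13 times its library median, whereas near 39843154 on chromosome 17 it was 34.5 times in W2 and 33.8 times in M6. A copy-number gain in the M6 cells may explain the Mycl segment, but this stays open, since the segment was picked by its background, which forces high pileups, and at its 10 shared sites pileups were 9.57 times those of W2 while background was 17.4 times. In the Nfib segment W2 had 0 peaks, so there a gain and a repeat effect cannot be told apart, and no sequence coverage or input DNA was used here.

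The excess of M6 peaks, 3.94 times those of W2, was weighed as sequencing depth, library-wide enrichment and biology. Deeper sequencing of M6, in tags that the caller used, is argued against by the background floor, 0.895 times that of W2. The floor cannot show a difference in mitochondrial tags, whose number is not given in the sources used here. Library-wide enrichment, a larger share of tags falling in open regions, may account for part of it, since shared gene-end sites had higher pileups in M6 by a median log2 of 0.58, and 17 of 18 shared sites at housekeeping gene ends were higher too. Whether that enrichment came from library preparation or from the tumor stage stays open with 1 library per stage, and the stage itself was not tested.

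The low share of neuroendocrine genes with a W2 peak among those with an M6 peak, 2 of 19, was weighed against library-wide enrichment and nerve tissue in the M6 sample. Enrichment acting alike on all gene ends is argued against as the whole cause, because the share lay at percentile 0.275 of strength-matched sets. Those sets were matched on the M6 −log10 q only, and the housekeeping list (16 of 23) lay above their middle 95%, at 99.89, so a share outside it is not particular to neuroendocrine genes. Channel genes (3 of 27) also lay below the middle 95%, at 0.26, while receptor genes (1 of 15) at 2.81, neural adhesion genes (1 of 11) at 5.93, nerve cell factors (0 of 4) at 7.56 and vesicle release genes (17 of 43) at 15.8 lay inside it, as did the values of 33.4 for hepatocyte (1 of 4), 48.7 for mesenchymal (1 of 5) and 93.3 for luminal genes (7 of 11), and M6 peaks of the neuroendocrine loci away from gene ends lay at 17.4 (2 of 47), within the range of matched draws. Nerve tissue in the sample and a neuroendocrine state of the tumor cells cannot be told apart, since the 4 nerve cell transcription factor genes with an M6 gene-end peak (Neurod4, Sox21, Sox1 and Phox2a) are not known to be lacking in neuroendocrine tumors. The difference in stage is the open biological explanation, and differences between animals or between fresh and cultured cells stay open as well.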

How the results depend on the processing

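The alternatives without raised background and the strength-matched share were added after the data were seen, and the others were planned. The motif alternatives were not run, since no sequence was used. No library could be left out with 1 per time point. No paired analysis was possible because each time point had 1 library and no test was made. Of 144 values under an alternative that answer a planned comparison or the 2 added ones on neuroendocrine and luminal genes, 102 stayed within the margin set for them, 31 moved and 11 changed sign. The 102 include the neuroendocrine gene-end difference, which went from 3 to 0 when peaks were ranked by fold. A change of that difference from 3 to 4 counted as moved, so these counts do not measure how well each result held. Leaving out peaks with raised background moved none beyond that margin.

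The ratio of peak numbers rose to 6.23 at a −log10 q of at least 10. The shared share of W2 peaks was 62.9% with summits within 100 bp, 51.8% with equal numbers of peaks, 81.6% at a −log10 q of at least 5 and 86.8% at 10 or more. That of M6 peaks was 16.0% with summits, 50.5% with equal numbers and 13.9% at a −log10 q of at least 10. The gene-end share in M6 minus W2 was −23.5 points with all peaks and −11.8 points ranked by fold.

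With all peaks, M6 minus W2 in genes with a gene-end peak was 17 (neuroendocrine), 4 (neuronal factors), 3 (luminal), 1 (basal), 4 (mesenchymal), 9 (cell cycle), 7 (housekeeping), 7 (immediate early) and 3 (hepatocyte). The luminal, basal, housekeeping and immediate early values reversed. Loci with more minus loci with fewer M6 peaks were then 25 (neuroendocrine), 11 (neuronal factors), 14 (luminal), 7 (basal), 6 (mesenchymal), 5 (fibroblast), 2 (smooth muscle), 3 (leukocyte), 7 (endothelial), 17 (cell cycle), 19 (housekeeping), 14 (immediate early) and 6 (hepatocyte), and the luminal, basal, mesenchymal, smooth muscle, leukocyte, cell cycle and housekeeping values reversed. The larger M6 list can raise these counts, and among length-matched lists with the same peaks a list with few peaks then falls to a low percentile. Endothelial genes, with gene-end peaks at 0 genes in both libraries, lay at percentile 1.365. The low values of 5.13 for luminal, 2.66 for basal and 0.335 for smooth muscle genes therefore cannot be read as a loss. The gene-end difference lay at percentile 99.9 for neuroendocrine genes (random median 8) and 98.95 for immediate early genes. The loci lay at 99.96 for neuroendocrine and 99.995 for immediate early genes.

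Gene ends of 500 bp gave a neuroendocrine difference of 4 and those of 2.5 kb one of 4, with −4 for luminal genes at 2.5 kb. Ranking by fold gave 0 for neuroendocrine, −5 for luminal, −10 for housekeeping and −5 for immediate early genes. Loci with 50 kb on either side gave −4 (basal), −4 (leukocyte) and 4 (endothelial). The neuroendocrine genes also found in W2 made 0% at 500 bp (0 of 17, percentile 0.005) and 9.09% at 2.5 kb (percentile 0.05), and those of nerve cell factors 0% at 2.5 kb (0 of 6), where the percentile fell to 1.92 from 7.56. The cause of the changes with window and ranking was not tested. The peak lists limit what can be seen: W2 peaks had at least 12 tags and M6 peaks at least 10. Of 30 housekeeping genes, 16 had a W2 gene-end peak and 23 an M6 one. By the background floor, 0.895 times that of W2 in M6, W2 was not the shallower library.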

Other observations

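The gene families below were picked after the lists had been seen. The test of peaks away from gene ends was chosen after the length-matched test had been seen and before its own result. The peak counts at the loci were known by then, and for adhesion genes they largely set the outcome.

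Genes of neural adhesion and axon guidance carried many M6 peaks and few W2 peaks. With all peaks, the loci of 42 such genes (contactins, teneurins, Robo and Slit genes and others) held 160 M6 and 7 W2 peaks. Single genes in this paragraph were named after their values were seen. Its counts were not adjusted for gene length, so a long gene can hold many M6 peaks by its length alone. Lsamp, a neuronal adhesion protein, had 14 M6 peaks and 0 in W2, Tenm4, a teneurin, 14 and 0, and Cntnap2, a contactin-associated protein, 11 and 0. The loci of 134 voltage-gated channel genes held 223 M6 and 24 W2 peaks, with 12 M6 and 0 W2 peaks at the calcium channel gene Cacna1e. Vesicle release genes held 142 and 34, neurotransmitter receptor genes 53 and 6, and claudin and keratin genes 48 and 9. For comparison, ribosomal protein genes held 112 and 45, proteasome genes 55 and 20, and the 1110 olfactory receptor genes 19 and 3.

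One hypothesis was that regions near neural genes opened in M6 beyond the general excess of peaks. With equal numbers of peaks, the difference lay at percentile 99.9 of length-matched lists for channels, 82.8 for receptors, 98.0 for vesicle release, 99.9 for adhesion and 81.6 for claudins and keratins. That test cannot decide, since olfactory receptor genes, with 3 peaks in each library, lay at percentile 100. At matched −log10 q, M6 peaks away from gene ends were shared with W2 in 2 of 146 cases near adhesion genes (1.37%, percentile 0.005). Near channel genes they were shared in 5 of 172 (2.91%, percentile 0.12). The share was 9.18% over the 14079 such peaks used, which are fewer than all M6 peaks away from gene ends. It was 8.89% for those at the 4196 longest other genes. Vesicle release genes, with 5 of 78 (6.41%, percentile 17.9), and receptor genes, with 1 of 30 (3.33%, percentile 13.0), left it open, as did claudin and keratin genes, which are not neural, with 1 of 23 (4.35%, percentile 31.9). For adhesion genes the low share cannot decide. Their loci held 7 W2 peaks, so only about 7 of the 146 M6 peaks could be shared, near the lower limit of the matched draws (4.79%). The share there restates the small number of W2 peaks. Peaks at 1 locus are not independent, so the percentiles describe these 2 libraries. A gain in the late-stage cells may hold for channel genes but was not seen for every neural family tested.

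By the same measure, M6 peaks away from gene ends near the 38 neuroendocrine genes were shared in 2 of 47 cases (4.26%, percentile 17.4), those near the 34 luminal genes in 6 of 26 (23.1%, percentile 98.9) and those near immediate early genes in 4 of 10 (40.0%, percentile 99.6). Chromosome X held 39 W2 peaks (0.680%) and 370 M6 peaks (1.64%).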
